A study of Mus musculus with 24 samples.

How the data were processed

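Total RNA of 24 mouse livers, from control and DNMT1 knockout mice at weeks 4, 8 and 20, was isolated with a column kit, amplified to biotin-labelled cRNA and hybridised to an Illumina mouse expression array, per the labels' protocols. Background subtraction and normalization were done by the authors in GenomeStudio 2011, per the labels' processing notes. The deposited series table holds linear intensity, 1 value per probe and array, for 25697 probes. Of these values 27.8% lay below 0, which background subtraction leaves, and the sorted columns were nearly identical between arrays, which quantile normalization leaves, with column medians between 13.3 and 13.6. A separate non-normalized table has 48 columns, 24 of signal and 24 of detection p-values, whose names match no sample in the labels. Those columns were not used here, and only the pairing of probe and gene symbol was read from that table. The plan fixed before the data were examined was to normalize the non-normalized signals. Since they cannot be assigned to samples, the plan's fallback was followed and the deposited normalized intensity was used without a further normalization.

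Values were set to at least 0 and transformed as log2(intensity + 16). The SD of the noise was 7.03, taken as the root mean square of the negative values, and a probe was counted as above background at an intensity over 16.3, the noise SD times 2.33 (one-sided p of 0.01). These choices were made after the distribution of the values had been seen and before any test. Probes above background on at least 4 of the 24 arrays were kept (14536), and each gene was represented by its probe of highest mean, which left 10733 genes. Older symbols were replaced through a RefSeq gene table of assembly GRCm38.p6, which was used for names and gene order only. Of the probes, 20733 had a current symbol, 3872 an older one that was updated and 1061 kept the symbol of the file, and 31 symbols damaged by date conversion were left unnamed. Where a gene had other probes, their values were compared with the one used, and those whose call differed are given. A fold given as "at least" compares the group above background with the background threshold where no array of the other group was above it.

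All tests were two-sided. One model with 6 group means over all 24 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), and p-values were adjusted over the 10733 genes by the method of Benjamini and Hochberg with a threshold of 0.05. Contrasts were knockout minus control at each week, the change of this difference between weeks, and the change with age within a genotype. Adjusted p-values of genes in groups of 4 arrays all come from limma. Dnmt1 was also tested by exact permutation of the log2 values. The replicate numbers of the labels do not say which arrays belong together, so arrays were not paired. No covariate was used, since the labels give no chip or batch.

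A total of 31 gene lists was fixed before the data were examined. They cover DNA methylation machinery, imprinted, germline and fetal liver genes, p53 targets, senescence and secretory phenotype, DNA replication and G1/S, mitosis and G2/M, biliary and progenitor markers, stellate cell and matrix genes, markers of macrophages, T and NK cells, B and plasma cells, neutrophils and endothelium, erythroid genes, hepatocyte plasma proteins and amino acid enzymes, cytochrome P450 genes, bile acid synthesis and transport, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and PPAR alpha targets, acute phase genes, interferon response, MHC class II, NRF2 and glutathione genes, pericentral and periportal hepatocyte genes, male-biased and female-biased liver genes, and sex chromosome transcripts. Each was tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over the 93 tests of 31 lists in 3 weeks. The list tests of the changes from week 4 to 8 and from week 8 to 20 were adjusted together as a separate family. Members past the threshold were also counted with p-values adjusted over the list alone. Some genes stand in more than 1 list.

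Genes were named by a rule fixed before the data were examined. In each knockout-control comparison these were the 10 genes of largest rise and the 10 of largest fall past the threshold whose arrays did not overlap between groups, passing over unnamed models. In each change with age the 5 largest in each direction were taken. Not every gene that the rule names is given. For each list the 4 members of lowest p could be named, of which those printed were picked from that set, together with the sex chromosome transcripts. Dnmt1, Dnmt3a, Dnmt3b, Uhrf1, Afp, H19, Igf2, Cdkn1a and Mki67 were to be given in every comparison, and Mki67 was not on the array.

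The week 8 test was tried in 3 simulated runs over 10733 genes, with 50 changed at each size. Changes of 0.5, 1, 2 and 3 on the log2 scale were recovered at 18.0%, 76.0%, 98.7% and 100%, with 7.67 false calls per run. The real test called 5247, so its rates may differ. Alternatives tried were an offset of 50 after normexp, a floor of 1 with a new quantile normalization, a floor of 16, cyclic loess, no filter on dim probes or a filter at 12 arrays, all probes tested singly, eBayes without trend or with robust estimation, array weights, only the 8 arrays compared, the replicate number as a block, an estimated inter-gene correlation, each array left out in turn, and both doubtful control arrays left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.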

Results

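Transcripts of mouse liver were measured on an Illumina expression array in 24 samples, 12 from control mice and 12 from mice given as knockouts of DNMT1, the maintenance DNA methyltransferase that copies methylation marks onto newly made DNA. Livers were taken at weeks 4, 8 and 20, with 4 arrays for each genotype at each week, and nothing in the labels says whether the 4 arrays of a group come from separate animals, so p-values measure only the spread between these arrays. Between 12182 and 12268 of the 25697 probes lay above background on each array, and 10733 genes could be tested. Differences below are knockout minus control on the log2(intensity + 16) scale, given as difference ± SE with 4 arrays per group. This scale understates the change of weakly expressed genes, and for some of the genes at background in all arrays of one group a lower bound of the fold is given. For the others of that kind the printed difference does not measure the fold. A few arrays stood apart from their groups. Control week 20 replicates 3 and 4 lay at 34.8 and 35.1 on the third principal component, which held 6.55% of the variance, against -10.8 and -8.62 for replicates 1 and 2. The mean log2 signal of the acute phase genes was 12.9 and 12.8 on those arrays, against 10.3 and 10.4 on the other control arrays of that week. Knockout week 8 replicate 4 had a log2 signal of 4.00, the floor of the scale, for the Y-linked gene Eif2s3y, against 9.13 to 9.27 on the other knockout arrays of that week.

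Dnmt1 itself was read by 1 probe, and its transcript was lower in knockout livers at every week, past no adjusted threshold by limma. The difference was -0.25 ± 0.19 at week 4 (adjusted p = 0.364, exact two-sided permutation p = 0.371). It was -0.30 ± 0.19 at week 8 (adjusted p = 0.20, exact permutation p = 0.0286, the smallest that 70 arrangements allow). At week 20 it was -0.58 ± 0.19 (adjusted p = 0.0737, exact permutation p = 0.0571). Knockout intensity + 16 was 84.2%, 81.1% and 66.8% of control at weeks 4, 8 and 20. Group means ± SD of the log2 signal were 6.76 ± 0.34, 6.84 ± 0.09 and 6.64 ± 0.20 in controls and 6.52 ± 0.37, 6.54 ± 0.11 and 6.06 ± 0.33 in knockouts at weeks 4, 8 and 20 (n = 4 each). Where the probe lies relative to the deleted part of the gene is not given in the sources used here. A probe outside that part would still bind a shortened transcript, so these values do not check the deletion. The probes of Dnmt3a, a methyltransferase that sets new marks, were at background on every array. Dnmt3b, its paralog, differed by 0.12 ± 0.36, 0.045 ± 0.36 and -0.67 ± 0.36 at weeks 4, 8 and 20 (adjusted p = 0.841, 0.926 and 0.286). Uhrf1, which brings DNMT1 to replicating DNA, rose by 1.45 ± 0.38 at week 4 (adjusted p = 0.00531) and 3.49 ± 0.38 at week 8 (adjusted p = 4.0e-08) and differed by 0.16 ± 0.38 at week 20 (adjusted p = 0.85). The week 4 value of Uhrf1 was 1.61 with an adjusted p of 0.128 when values were floored at 1 and quantile normalized again.

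**Figure D1:**
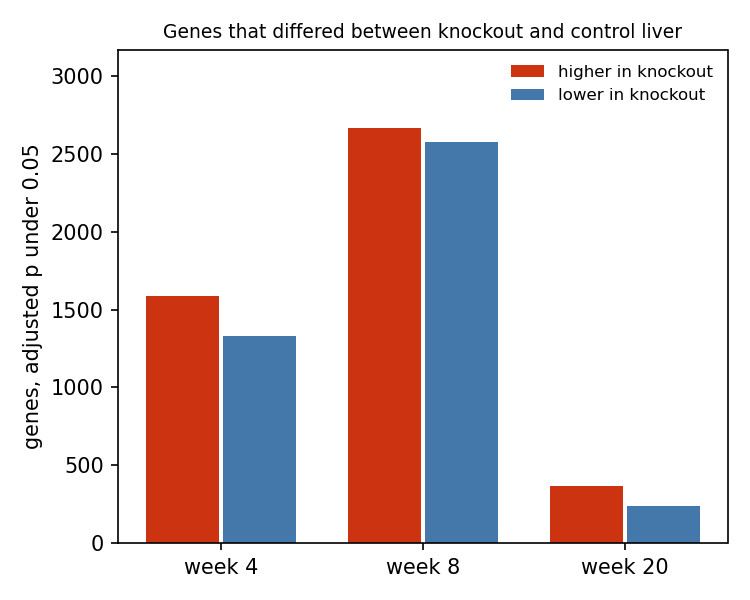
Number of genes that were higher (red) or lower (blue) in knockout than in control liver at adjusted p under 0.05, at each week. The counts rose from 1587 higher and 1331 lower at week 4 to 2670 and 2577 at week 8, and were 369 and 239 at week 20.

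The week 4 comparison asks which transcripts differ between knockout and control liver in young mice. Bglap3, a gene of the osteocalcin family of bone proteins, rose by 8.42 ± 0.27, at least 447-fold, and Rhox5, an X-linked homeobox gene of the testis, rose by 7.47 ± 0.28, at least 281-fold. Further rises were seen for Pkd1l2 (7.19 ± 0.32), Slpi (7.15 ± 0.73), a secreted protease inhibitor, and Bglap1 (6.64 ± 0.29). The glutathione transferases Gstp2 (6.62 ± 0.48) and Gsta1 (5.68 ± 0.76) rose, as did Tex19.1 (6.41 ± 0.31), a germline gene, Ly6d (5.88 ± 0.34) and Ntrk2 (5.60 ± 0.30), a neurotrophin receptor. The largest falls were in Rgs16 (-5.07 ± 1.05), a regulator of G protein signalling, Inmt (-4.19 ± 0.68), a methyltransferase of small amines, Thrsp (-3.98 ± 0.53), which promotes fat synthesis, and Sult2a8 (-3.47 ± 0.38), a sulfotransferase. Upp2 (-2.71 ± 0.69), Cela2a (-2.68 ± 0.76), Ces1e (-2.59 ± 0.49), Cpsf4l (-2.58 ± 0.31), Fn3k (-2.50 ± 0.31) and Spata2L (-2.42 ± 0.37) also fell. In all, 1587 genes were higher and 1331 lower, with a difference of at least 2-fold for 590 and 307 of them. Probes of close paralogs such as Bglap1 and Bglap3, Gstp2, Gsta1 or Tex19.1 may bind transcripts of their relatives, so which member of each family changed is uncertain. Other probes gave 0.97 and 4.58 for Bglap1 and 1.42 for Ntrk2. The call of Cela2a ended in a fit of the 8 arrays of that week alone (adjusted p = 0.0625).

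Many germline, oxidant defence and interferon genes rose at week 4. Of 25 measured germline genes, which DNA methylation silences in body tissues, 17 rose and 1 fell (17 and 1 over the list alone), with Dpep3 (5.38 ± 0.36) and Magea2 (4.55 ± 0.31) among those that rose. Germline genes as a list had a median of 1.41 (camera adjusted p = 1.5e-10, 0.0776 with an estimated correlation). The list of NRF2 targets and glutathione genes, which protect against oxidants, held 14 higher and 0 lower of 21 members (14 and 0 over the list alone), with rises of Cbr3 (5.08 ± 0.31), Gstm3 (3.46 ± 0.27) and Srxn1 (2.40 ± 0.24). NRF2 and glutathione genes had a median of 0.92 (camera adjusted p = 4.4e-09, 0.128 with an estimated correlation). Interferon response genes rose for 22 of 28 and fell for 0 (24 and 0 over the list alone). The interferon list had a median of 1.13 (camera adjusted p = 1.8e-12, 0.116 with an estimated correlation). Examples were Oasl2 (2.18 ± 0.19) and Irf7 (2.21 ± 0.23), an antiviral protein and a transcription factor of the response. MHC class II genes, which present antigen, rose for 6 of 8 and fell for 0 (6 and 0 over the list alone), including H2-Eb1 (1.45 ± 0.25) and Cd74 (1.29 ± 0.26). The MHC class II list had a median of 1.01 (camera adjusted p = 6.6e-04, 0.281 with an estimated correlation). Among macrophage markers, 19 of 23 rose and 0 fell (21 and 0 over the list alone), with Gpnmb (4.72 ± 0.30), Lgals3 (2.40 ± 0.22) and Cd68 (1.88 ± 0.30) as examples, although another Gpnmb probe gave 0.63 ± 0.24 (adjusted p = 0.0524). Macrophage markers had a median of 0.99 (camera adjusted p = 2.3e-10, 0.151 with an estimated correlation). Stellate cell and matrix genes, of the scar-forming cells of the liver, were higher for 14 and lower for 1 of 29 (16 and 1 over the list alone), with Timp1 (2.71 ± 0.33) and Lum (1.48 ± 0.22) rising. Matrix genes had a median of 0.58 (camera adjusted p = 7.7e-05, 0.28 with an estimated correlation).

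Growth control genes also moved at week 4. Mitosis and G2/M genes were higher for 9 and lower for 0 of 16 (12 and 0 over the list alone), with rises of Kif22 (1.57 ± 0.26), Plk1 (1.62 ± 0.35) and Prc1 (1.47 ± 0.30), which act in spindle assembly and cell division. The mitosis list had a median of 0.93 (camera adjusted p = 6.9e-05, 0.28 with an estimated correlation). DNA replication and G1/S genes were higher for 8 and lower for 0 of 24 (8 and 0 over the list alone), with Ccnd1 (1.58 ± 0.23), cyclin D1, and Mcm2 (1.09 ± 0.23), a replication helicase subunit. The replication list had a median of 0.34 (camera adjusted p = 0.0234, 0.449 with an estimated correlation). Targets of p53 rose for 11 of 25 and fell for 2 (12 and 3 over the list alone), with Phlda3 (2.38 ± 0.28) and Gtse1 (1.96 ± 0.26) higher and Sesn2 (-1.34 ± 0.25) lower. The p53 list had a median of 0.48 (camera adjusted p = 0.00645, 0.163 with an estimated correlation). Cdkn1a, the p53 target that stops the cell cycle, differed by 1.67 ± 0.66 (adjusted p = 0.0633), and its 2 other probes gave 1.34 ± 0.42 and 1.04 ± 0.53 (adjusted p = 0.0199 and 0.154). Its adjusted p was 0.0215 with an offset of 50, 0.0121 with array weights and 1.1e-04 with only the 8 arrays. The senescence and secretory list had 10 higher and 2 lower of 19 (12 and 2 over the list alone), with Mmp12 (2.55 ± 0.28), a matrix protease, and Cxcl10 (2.33 ± 0.37), a chemokine. The senescence list had a median of 0.70 (camera adjusted p = 5.3e-04, 0.0832 with an estimated correlation). Imprinted genes were higher for 6 and lower for 2 of 16 (6 and 2 over the list alone), with H19 (3.46 ± 0.39), Impact (1.92 ± 0.22) and Phlda2 (1.83 ± 0.35). Imprinted genes as a list had a median of 0.25 (camera adjusted p = 0.0472, 0.334 with an estimated correlation). Of the fetal liver genes, 3 of 10 rose and 0 fell (3 and 0 over the list alone), among them H19 and Igf2 (1.65 ± 0.46), a fetal growth factor, while Afp, alpha-fetoprotein, differed by 0.62 ± 0.31 (adjusted p = 0.147). Fetal liver genes had a median of 0.61 (camera adjusted p = 0.0394, 0.334 with an estimated correlation). Biliary and progenitor markers rose for 5 of 17 and fell for 0 (5 and 0 over the list alone), with Bicc1 (2.10 ± 0.25) and Spp1 (1.95 ± 0.25). Biliary markers had a median of 0.22 (camera adjusted p = 0.0394, 0.13 with an estimated correlation).

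Several lists of liver metabolism shifted down at week 4. Hepatocyte plasma proteins and amino acid enzymes were higher for 0 and lower for 20 of 36 (0 and 20 over the list alone), with F7 (-1.79 ± 0.21), a clotting factor, and Alb (-0.93 ± 0.16), albumin. The hepatocyte list had a median of -0.50 (camera adjusted p = 2.0e-06, 0.13 with an estimated correlation). Fatty acid synthesis genes fell for 6 of 15 and rose for 0 (0 and 11 over the list alone), with Pklr (-1.79 ± 0.37) and Fasn (-1.67 ± 0.35), fatty acid synthase. Fatty acid synthesis genes had a median of -0.95 (camera adjusted p = 3.4e-05, 0.251 with an estimated correlation). Cholesterol synthesis genes fell for 11 of 21 and rose for 0 (0 and 13 over the list alone), with Tm7sf2 (-1.70 ± 0.25) and Stard4 (-1.22 ± 0.24). Cholesterol synthesis genes had a median of -0.70 (camera adjusted p = 3.2e-05, 0.334 with an estimated correlation). Cytochrome P450 genes were higher for 2 and lower for 10 of 30 (3 and 11 over the list alone), with Cyp2c29 (-2.18 ± 0.35) and Cyp2d40 (-1.92 ± 0.26) falling and Cyp4a12b (4.86 ± 0.36) rising. The P450 list had a median of -0.38 (camera adjusted p = 0.0192, 0.362 with an estimated correlation). Female-biased liver genes fell for 3 of 9 and rose for 0 (0 and 3 over the list alone), with Hao2 (-2.23 ± 0.38) and Cyp2b13 (-1.92 ± 0.40) among them. Female-biased genes had a median of -0.63 (camera adjusted p = 0.0351, 0.334 with an estimated correlation). Male-biased liver genes went both ways, with 3 higher and 6 lower of 18 (5 and 6 over the list alone, median 0.13, camera adjusted p = 0.848), Gstp2 and Cyp4a12b rising and Hsd3b5 (-4.00 ± 0.66), a steroid dehydrogenase, falling. Bile acid genes also went both ways, with 5 higher and 7 lower of 17 (5 and 7 over the list alone, median -0.28, camera adjusted p = 0.485), a mean of 0.044 and a fall of Slc10a1 (-2.28 ± 0.21), the bile acid importer.

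The calls of 5 lists at week 4 rested on single arrays. Without control replicate 1 the adjusted p was 0.0760 for imprinted genes, 0.116 for fetal liver genes and 0.0703 for biliary markers, without knockout replicate 1 it was 0.162 for imprinted and 0.117 for fetal liver genes, and without control replicate 5 it was 0.144 for replication genes and 0.0544 for female-biased genes. With values floored at 1 and quantile normalized again it was 0.0663 for imprinted, 0.121 for fetal liver and 0.281 for female-biased genes, 0.0569 for Hao2 and 0.16 for Cyp2b13. With no filter on dim probes it was 0.127 for female-biased genes and 0.0338 for T and NK markers, and it was 0.0633 for biliary markers with a floor of 16 and 0.0737 for imprinted genes with the replicate block. Without knockout replicate 4, Afp rose by 0.94 (adjusted p = 0.0217). The remaining lists were past no threshold at week 4. DNA methylation machinery had 3 higher and 1 lower of 11 (3 and 1 over the list alone, median 0.12, camera adjusted p = 0.485). T and NK cell markers had 4 higher and 0 lower of 15 (4 and 0 over the list alone, median 0.54, camera adjusted p = 0.0955). B and plasma cell markers had 1 higher and 0 lower of 7 (1 and 0 over the list alone, median 0.0032, camera adjusted p = 0.848). Neutrophil markers had 0 higher and 1 lower of 11 (0 and 1 over the list alone, median 0.33, camera adjusted p = 0.822). Endothelial markers had 1 higher and 1 lower of 20 (1 and 0 over the list alone, median -0.14, camera adjusted p = 0.485), with Plvap (0.48 ± 0.12) rising. Erythroid genes had 1 higher and 1 lower of 10 (1 and 1 over the list alone, median -0.13, camera adjusted p = 0.79). Fatty acid oxidation genes had 3 higher and 2 lower of 21 (3 and 2 over the list alone, median -0.11, camera adjusted p = 0.66) and a mean of -0.0019. Acute phase genes had 1 higher and 3 lower of 22 (1 and 2 over the list alone, median -0.0014, camera adjusted p = 0.92) with a mean of 0.33, and Lcn2 rose by 5.46 ± 1.20. Pericentral hepatocyte genes had 2 higher and 2 lower of 14 (2 and 3 over the list alone, median -0.18, camera adjusted p = 0.819). Periportal hepatocyte genes had 1 higher and 6 lower of 16 (2 and 6 over the list alone, median -0.19, camera adjusted p = 0.339). The 5 sex chromosome transcripts had 1 higher and 0 lower of 5 (1 and 0 over the list alone, median -0.0050, camera adjusted p = 0.822), with Xist (2.05 ± 0.31), the RNA that silences an X chromosome, at least 4.03-fold higher.

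**Figure D2:**
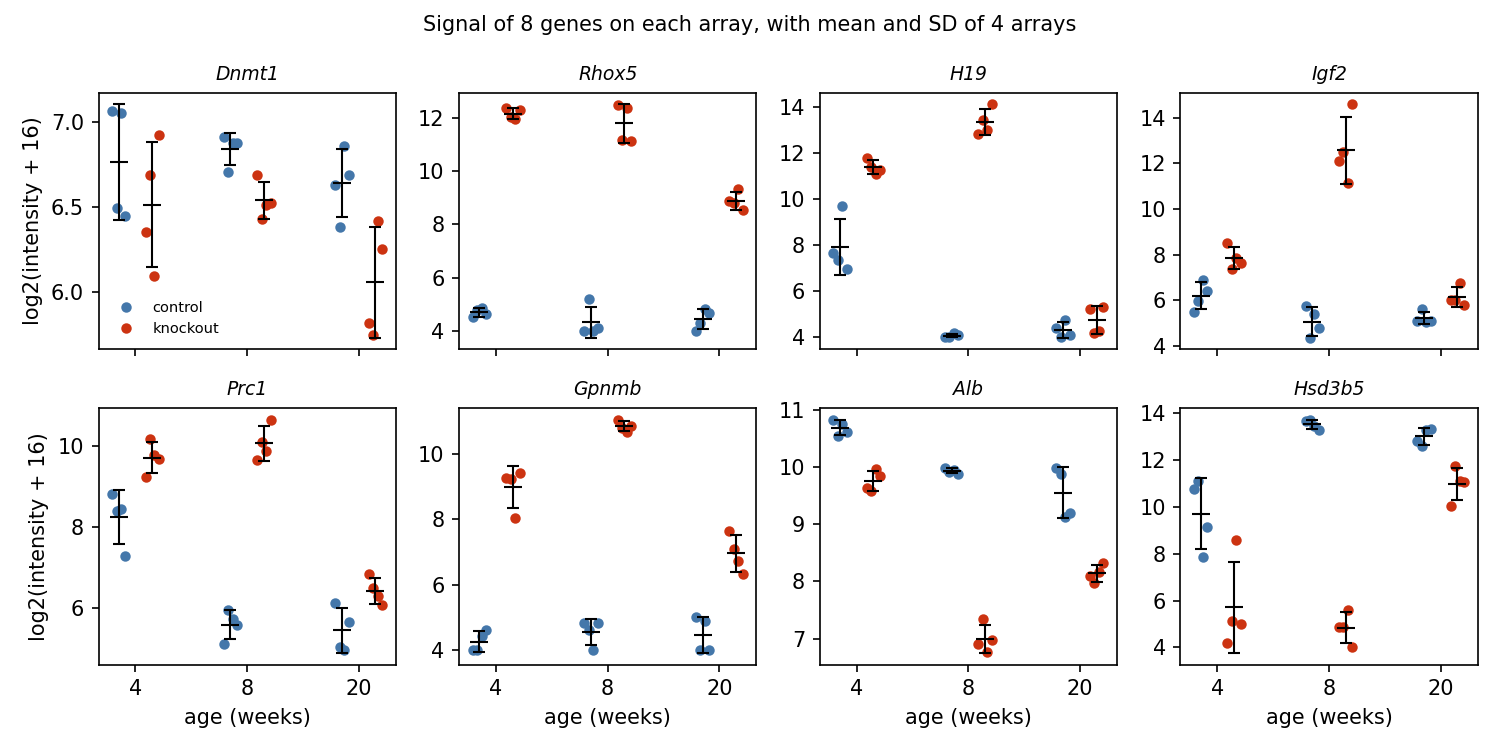
Signal of 8 genes on each array as log2(intensity + 16) against age in weeks, control arrays in blue and knockout arrays in red, with the mean and SD of 4 arrays. H19 and Igf2 rose by 9.28 and 7.51 in knockout livers at week 8 and fell again by week 20, while Rhox5 was higher at all 3 weeks.

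The week 8 comparison asks the same of adult mice, and 5247 genes were past the threshold. H19 and Igf2, an imprinted pair expressed in fetal liver, rose by 9.28 ± 0.39, at least 632-fold, and by 7.51 ± 0.46. Ly6d rose by 8.26 ± 0.34, at least 425-fold, and Rhox5 and Bglap3 rose by 7.47 ± 0.28 and 7.40 ± 0.27. Other large rises were those of Slc7a11 (6.94 ± 0.29), a cystine transporter, Cbr3 (6.62 ± 0.31), a carbonyl reductase, Slpi (6.48 ± 0.73), Lcn2 (6.38 ± 1.20), an iron-binding acute phase protein, and Tex19.1 (6.32 ± 0.31). Hsd3b5, a steroid dehydrogenase of male liver, had the largest fall (-8.70 ± 0.66). Sult2a8 (-7.18 ± 0.38), Rgs16 (-5.98 ± 1.05), Elovl3 (-5.95 ± 0.41), a fatty acid elongase of male liver, Thrsp (-5.69 ± 0.53), Dct (-4.64 ± 0.40) and Ces3b (-4.55 ± 0.32) fell too. The major urinary protein genes Mup4 (-6.64 ± 0.42), Mup5 (-5.06 ± 0.40) and Mup6 (-4.69 ± 0.50) fell, though their probes may bind transcripts of other members of the family. In all, 2670 genes were higher and 2577 lower, by at least 2-fold for 1366 and 733 of them.

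Fetal genes and genes of dividing cells rose at week 8. Of 10 measured fetal liver genes, 8 rose and 0 fell (8 and 0 over the list alone), including Gpc3 (5.20 ± 0.39), Igf2bp3 (4.28 ± 0.18) and Afp (3.49 ± 0.31). Fetal liver genes had a median of 3.88 (camera adjusted p = 3.1e-07, 0.0776 with an estimated correlation). All 16 measured mitosis and G2/M genes rose and 0 fell (16 and 0 over the list alone), among them Prc1 (4.47 ± 0.30), Ccnb1 (3.64 ± 0.29), Top2a (3.41 ± 0.30) and Birc5 (3.32 ± 0.30). The mitosis list had a median of 2.99 (camera adjusted p = 1.5e-10, 0.121 with an estimated correlation). DNA replication and G1/S genes rose for 22 of 24 and fell for 0 (22 and 0 over the list alone), with Ccnd1 (3.89 ± 0.23), Mcm5 (2.66 ± 0.25) and Mcm6 (2.50 ± 0.29). The replication list had a median of 1.18 (camera adjusted p = 1.1e-07, 0.121 with an estimated correlation). Targets of p53 were higher for 16 and lower for 3 of 25 (16 and 3 over the list alone), with Ddit4l (4.02 ± 0.24), Phlda3 (3.88 ± 0.28), Gtse1 (2.69 ± 0.26) and Cdkn1a (3.76 ± 0.66). The p53 list had a median of 0.91 (camera adjusted p = 0.00161, 0.129 with an estimated correlation). The senescence and secretory list had 14 higher and 0 lower of 19 (14 and 0 over the list alone), with Cdkn2b (2.93 ± 0.25), Timp1 (3.29 ± 0.33) and Mmp13 (3.38 ± 0.34). The senescence list had a median of 1.39 (camera adjusted p = 4.9e-06, 0.0421 with an estimated correlation). Another Mmp13 probe gave -0.026 ± 0.27. Of all lists and weeks, this list at week 8 alone held its call with an estimated correlation. Germline genes rose for 15 of 25 and fell for 2 (16 and 2 over the list alone), with Magea2 (5.34 ± 0.31) and Magea5 (4.85 ± 0.30), although another Magea5 probe gave -0.30 ± 0.31. The germline list had a median of 1.47 (camera adjusted p = 1.2e-05, 0.129 with an estimated correlation). Imprinted genes rose for 10 of 16 and fell for 2 (10 and 2 over the list alone), with Phlda2 (3.41 ± 0.35) and Impact (2.07 ± 0.22) beside H19 and Igf2. Imprinted genes as a list had a median of 0.89 (camera adjusted p = 0.00117, 0.13 with an estimated correlation). Biliary and progenitor markers rose for 9 of 17 and fell for 1 (11 and 1 over the list alone), with Cldn4, at least 33.8-fold higher, Bicc1 (3.50 ± 0.25) and Spp1 (2.76 ± 0.25), osteopontin. Biliary markers had a median of 1.15 (camera adjusted p = 0.00391, 0.0832 with an estimated correlation).

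Markers of immune and scar-forming cells rose at week 8, while endothelial markers went both ways. Of 23 macrophage markers, 22 rose and 0 fell (22 and 0 over the list alone), with Gpnmb (6.26 ± 0.30), by another probe 2.14, Trem2 (4.02 ± 0.33), Lgals3 (3.60 ± 0.22) and Fcer1g (3.22 ± 0.22). Macrophage markers had a median of 2.22 (camera adjusted p = 1.1e-12, 0.129 with an estimated correlation). Stellate cell and matrix genes rose for 26 of 29 and fell for 0 (26 and 0 over the list alone), with Lum (3.51 ± 0.22), Mmp2 (3.35 ± 0.18) and Thbs2 (3.10 ± 0.25). Matrix genes had a median of 1.75 (camera adjusted p = 1.1e-12, 0.0832 with an estimated correlation). T and NK cell markers rose for 11 of 15 and fell for 0 (11 and 0 over the list alone), with Klrd1 (2.69 ± 0.30), Ccl5 (2.58 ± 0.22), Cd8b1 (2.42 ± 0.23) and Thy1 (2.38 ± 0.28). T and NK markers had a median of 0.99 (camera adjusted p = 3.3e-04, 0.0832 with an estimated correlation). Neutrophil markers rose for 10 of 11 and fell for 0 (10 and 0 over the list alone), with S100a8 (4.24 ± 0.58) and S100a9 (3.96 ± 0.48). Neutrophil markers had a median of 1.84 (camera adjusted p = 1.4e-04, 0.13 with an estimated correlation). B and plasma cell markers rose for 5 of 7 and fell for 0 (5 and 0 over the list alone), with Cd79b (1.68 ± 0.22) and Cd22 (1.30 ± 0.21). B and plasma cell markers had a median of 0.83 (camera adjusted p = 0.0394, 0.129 with an estimated correlation). MHC class II genes rose for 7 of 8 and fell for 0 (8 and 0 over the list alone), with Ciita (1.40 ± 0.26) and H2-DMb1 (1.31 ± 0.20). The MHC class II list had a median of 1.22 (camera adjusted p = 0.00154, 0.323 with an estimated correlation). Interferon response genes rose for 22 of 28 and fell for 1 (22 and 1 over the list alone), with Rsad2 (3.56 ± 0.29), Oasl2 (3.20 ± 0.19) and Ifit3 (2.53 ± 0.24). The interferon list had a median of 1.44 (camera adjusted p = 1.5e-09, 0.129 with an estimated correlation). NRF2 and glutathione genes rose for 17 of 21 and fell for 1 (17 and 1 over the list alone), with Srxn1 (3.72 ± 0.24) and Pgd (2.48 ± 0.19). NRF2 and glutathione genes had a median of 1.90 (camera adjusted p = 1.4e-08, 0.129 with an estimated correlation). Endothelial markers had 3 higher and 6 lower of 20 (3 and 7 over the list alone, median -0.15, camera adjusted p = 0.429), Plvap (1.25 ± 0.12) rising and Dnase1l3 (-1.08 ± 0.14) falling.

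Several lists of liver metabolism shifted down at week 8, and the sex-biased lists moved apart. Hepatocyte plasma proteins and amino acid enzymes rose for 1 of 36 and fell for 23 (1 and 23 over the list alone), with Alb (-2.94 ± 0.16), Otc (-2.74 ± 0.22), a urea cycle enzyme, and F7 (-2.33 ± 0.21). The hepatocyte list had a median of -0.72 (camera adjusted p = 2.0e-06, 0.13 with an estimated correlation). Cytochrome P450 genes were higher for 6 and lower for 18 of 30 (6 and 18 over the list alone), with falls of Cyp2c29 (-4.49 ± 0.35) and Cyp2d40 (-3.13 ± 0.26). The P450 list had a median of -0.74 (camera adjusted p = 7.0e-04, 0.214 with an estimated correlation). Bile acid genes were higher for 3 and lower for 9 of 17 (3 and 10 over the list alone), with Baat (-2.21 ± 0.16), Slc10a1 (-2.31 ± 0.21) and Cyp27a1 (-1.30 ± 0.10). Bile acid genes had a median of -0.70 (camera adjusted p = 0.0102, 0.13 with an estimated correlation). Fatty acid synthesis genes fell for 11 of 15 and rose for 0 (0 and 11 over the list alone), with Mlxipl (-1.93 ± 0.20), a regulator of the pathway, and Pklr (-2.34 ± 0.37). Fatty acid synthesis genes had a median of -1.34 (camera adjusted p = 2.2e-04, 0.314 with an estimated correlation). Male-biased liver genes fell for 14 of 18 and rose for 1 (1 and 15 over the list alone), with Hsd3b5, Elovl3, Ugt2b1 (-3.78 ± 0.21) and Nudt7 (-2.51 ± 0.18). Male-biased genes had a median of -2.23 (camera adjusted p = 2.6e-07, 0.121 with an estimated correlation). Female-biased liver genes rose for 5 of 9 and fell for 0 (5 and 0 over the list alone), with Cyp2b13 (3.03 ± 0.40), A1bg (3.56 ± 0.66) and Cyp2b9 (3.98 ± 0.86), the Cyp2b probes being ones that may bind paralogs. Female-biased genes had a median of 2.74 (camera adjusted p = 0.0234, 0.323 with an estimated correlation). On knockout replicate 4, the array with Eif2s3y at the floor, the log2 signal of Cyp2b9 was 11.1 against 7.24 to 7.90 on the other knockout arrays, and without it the list medians were -2.21 and 2.21. The 5 sex chromosome transcripts had 1 higher and 1 lower of 5 (1 and 2 over the list alone, median -0.74, camera adjusted p = 0.547), with Uty (-0.74 ± 0.24) falling, Xist (1.03 ± 0.31) rising, and values of -0.71 ± 0.47 for Ddx3y and -1.35 ± 0.67 for Eif2s3y (adjusted p = 0.216 and 0.0986). The median of this list was -0.052 without replicate 4, and the adjusted p of Xist was then 0.0589. The adjusted p of Uty was 0.0696 without control replicate 4, and that of Eif2s3y was 0.0449, 0.0431 and 0.0382 without knockout replicates 1, 2 and 3.

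The remaining lists were past no threshold at week 8. DNA methylation machinery had 3 higher and 1 lower of 11 (2 and 1 over the list alone, median 0.26, camera adjusted p = 0.432). Erythroid genes had 3 higher and 3 lower of 10 (3 and 3 over the list alone, median 0.18, camera adjusted p = 0.764) with a mean of -0.11. Cholesterol synthesis genes had 2 higher and 6 lower of 21 (2 and 5 over the list alone, median -0.33, camera adjusted p = 0.178), and without knockout replicate 4 their adjusted p was 0.0206 with a median of -0.56. Fatty acid oxidation genes had 4 higher and 7 lower of 21 (4 and 7 over the list alone, median -0.13, camera adjusted p = 0.577) with a mean of 0.12. Acute phase genes had 3 higher and 3 lower of 22 (3 and 3 over the list alone, median -0.029, camera adjusted p = 0.848) with a mean of 0.21. Pericentral hepatocyte genes had 3 higher and 4 lower of 14 (3 and 4 over the list alone, median -0.26, camera adjusted p = 0.556) with a mean of 0.12. Periportal hepatocyte genes had 4 higher and 7 lower of 16 (4 and 8 over the list alone, median -0.38, camera adjusted p = 0.231). When values were floored at 1 and quantile normalized again, the adjusted p was 0.0529 for female-biased genes, and without knockout replicate 3 it was 0.0541 for B and plasma cell markers, whose value with no filter on dim probes was 0.0756. With the floor of 1 it was 0.102 for Xist.

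**Figure D3:**
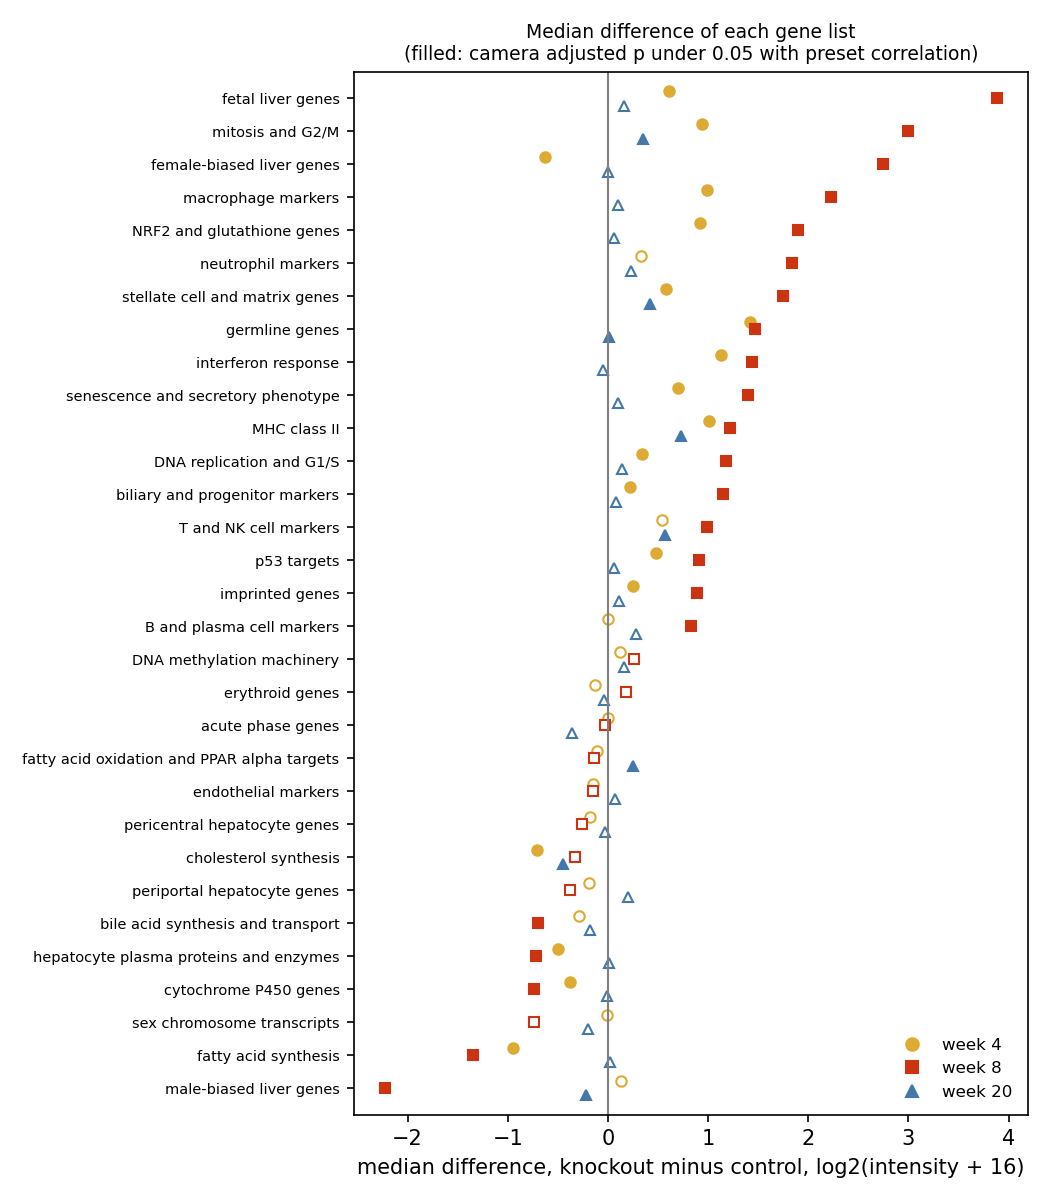
Median knockout minus control difference of each of 31 gene lists in log2(intensity + 16) at week 4 (circles), week 8 (squares) and week 20 (triangles), sorted by the week 8 median. Filled symbols mark camera adjusted p under 0.05 with the preset correlation, which 18, 22 and 8 lists reached at weeks 4, 8 and 20, and which 0, 1 and 0 reached with an estimated correlation.

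The week 20 comparison asks what differs in older mice, and 608 genes were past the threshold. Bglap3 rose by 4.89 ± 0.27, at least 29.9-fold, and Rhox5 by 4.44 ± 0.28, at least 27.9-fold. Wfdc15b (3.34 ± 0.37), Ntrk2 (3.34 ± 0.30), Cidec (3.27 ± 0.59), a lipid droplet protein, and Noct (2.90 ± 0.40), a protein of daily rhythm, rose too. Magea2 (2.85 ± 0.31), a germline gene of the X chromosome, Bglap1 (2.71 ± 0.29) and Gpnmb (2.48 ± 0.30) also rose, as did Iap (2.62 ± 0.23), a probe whose target is not given in the sources used here. Fgb, a fibrinogen chain, fell (-2.66 ± 0.29), and Gna14 (-2.52 ± 0.23), Sult5a1 (-2.32 ± 0.33), Susd4 (-1.94 ± 0.31), Serpine2 (-1.83 ± 0.31) and Cela1 (-1.74 ± 0.24) fell as well. Further falls were in Acpp (-1.71 ± 0.36), Cyp2u1 (-1.71 ± 0.27), Cd163 (-1.62 ± 0.31), a macrophage receptor, and Ppp1r3c (-1.54 ± 0.25), which guides glycogen synthesis. In all, 369 genes were higher and 239 lower, by at least 2-fold for 132 and 49 of them. H19, Igf2, Afp and Cdkn1a differed by 0.42 ± 0.39, 0.93 ± 0.46, -0.26 ± 0.31 and 0.10 ± 0.66 (adjusted p = 0.575, 0.25, 0.686 and 0.955). Other probes of Ntrk2, Bglap1, Gpnmb, Magea5 and Birc5 passed no threshold at week 20, with differences of 0.35 for Ntrk2, 0.19 and 1.0 for Bglap1, -0.11 for Gpnmb, 0.15 for Magea5, and 0.47 and 0.30 for Birc5. Another probe of Wfdc15b gave 1.09.

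At week 20, 8 lists passed with the preset correlation and 0 with an estimated one, and most of their members were past no threshold. Germline genes rose for 5 of 25 and fell for 0 (5 and 1 over the list alone), with Magea5 (2.44 ± 0.30) and Dpep3 (2.17 ± 0.36) beside Rhox5 and Magea2. The germline list had a median of 0.013 (camera adjusted p = 0.0394, 0.449 with an estimated correlation). Stellate cell and matrix genes were higher for 2 and lower for 2 of 29 (10 and 3 over the list alone), with Mmp2 (1.27 ± 0.18) and Lum (0.97 ± 0.22) rising and Lrat (-1.08 ± 0.27), a vitamin A storage enzyme, falling. Matrix genes had a median of 0.42 (camera adjusted p = 3.9e-04, 0.323 with an estimated correlation). MHC class II genes rose for 2 of 8 and fell for 0 (6 and 0 over the list alone), with H2-Eb1 (1.18 ± 0.25). The MHC class II list had a median of 0.73 (camera adjusted p = 5.1e-05, 0.189 with an estimated correlation), and of 0.46 without control replicates 3 and 4. T and NK cell markers were higher for 2 and lower for 1 of 15 (6 and 1 over the list alone), with Ccl5 (1.45 ± 0.22) and Klrd1 (1.06 ± 0.30) rising. T and NK markers had a median of 0.57 (camera adjusted p = 0.00493, 0.129 with an estimated correlation). Mitosis and G2/M genes rose for 1 of 16 and fell for 0 (2 and 0 over the list alone), the gene that rose being Birc5 (1.10 ± 0.30). The mitosis list had a median of 0.35 (camera adjusted p = 0.00376, 0.415 with an estimated correlation). Fatty acid oxidation genes rose for 3 of 21 and fell for 0 (4 and 0 over the list alone), namely Acot1 (2.30 ± 0.50), Angptl4 (0.70 ± 0.17) and Cyp4a14 (3.33, adjusted p = 0.049). Fatty acid oxidation genes had a median of 0.25 (camera adjusted p = 0.00131, 0.334 with an estimated correlation). Cholesterol synthesis genes fell for 2 of 21 and rose for 0 (0 and 4 over the list alone), namely Msmo1 (-0.99 ± 0.27) and Mvd (-1.63 ± 0.47). Cholesterol synthesis genes had a median of -0.45 (camera adjusted p = 3.2e-05, 0.334 with an estimated correlation). Male-biased liver genes fell for 2 of 18 and rose for 0 (1 and 4 over the list alone), with Susd4 among those that fell. Male-biased genes had a median of -0.22 (camera adjusted p = 0.0461, 0.509 with an estimated correlation).

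The week 20 count varied with single arrays. It was 284 without control replicate 3, 306 without control replicate 4, 331 without knockout replicate 2 and 370 without knockout replicate 3. Without control replicates 3 and 4, the arrays with high acute phase signal, 306 genes passed, and the differences of Cyp4a14 (0.47), Acot1 (1.11), Cidec (2.14), Acpp (-1.27), Cd163 (-0.75), H2-Eb1 (0.82), Msmo1 (-0.50) and Mvd (-0.67) were smaller and their calls ended. The calls of Klrd1 (1.22), Lrat (-0.99) and Angptl4 (0.64) ended too, with differences about as large as before in fewer arrays. The adjusted p was then 0.188 for cholesterol synthesis, 0.323 for fatty acid oxidation and 0.60 for male-biased genes. Without both arrays, lists of macrophage markers (median 0.51, adjusted p = 2.1e-07) and neutrophil markers (median 0.53, adjusted p = 0.016) were higher, and cytochrome P450 genes (median -0.14, adjusted p = 0.0067) and bile acid genes (median -0.26, adjusted p = 0.011) lower. Acute phase genes had 0 higher and 0 lower of 22 (0 and 0 over the list alone, median -0.36, camera adjusted p = 0.189) with all arrays, and a median of 0.51 without both. In a fit of the 8 arrays alone the calls of Serpine2 (adjusted p = 0.0514), Acpp (0.0955), Cd163 (0.094), H2-Eb1 (0.064), Klrd1 (0.155), Msmo1 (0.121), Mvd (0.132), Acot1 (0.10), Angptl4 (0.128) and Cyp4a14 (0.23) ended. The calls of Klrd1, Birc5, Lrat, Angptl4, Msmo1, Mvd and Cyp4a14 also ended when other single arrays were left out, and germline genes had an adjusted p of 0.166 without control replicate 1 and 0.0832 without control replicate 2. The adjusted p of male-biased genes was 0.113 and 0.106 without control replicates 3 and 4 and 0.0527 and 0.0556 without knockout replicates 1 and 4. Macrophage markers reached 0.00738 and 8.1e-04 without control replicates 3 and 4 and 0.0304 and 0.00278 without knockout replicates 2 and 3. Acute phase genes reached 5.5e-04 and 0.00181 without control replicates 1 and 2, and periportal genes 0.0148 without knockout replicate 2.

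Lists past no threshold at week 20 held few changed genes. Hepatocyte plasma proteins and amino acid enzymes had 1 higher and 4 lower of 36 (1 and 4 over the list alone, median 0.0075, camera adjusted p = 0.556) with a mean of -0.083, and Alb (-1.41 ± 0.16) fell. Cytochrome P450 genes had 1 higher and 1 lower of 30 (1 and 1 over the list alone, median -0.013, camera adjusted p = 0.851) with a mean of 0.011. Macrophage markers had 2 higher and 0 lower of 23 (3 and 0 over the list alone, median 0.11, camera adjusted p = 0.080). Biliary and progenitor markers had 1 higher and 0 lower of 17 (1 and 0 over the list alone, median 0.084, camera adjusted p = 0.78), with Bicc1 (1.46 ± 0.25) rising. Fetal liver genes had 0 higher and 0 lower of 10 (0 and 0 over the list alone, median 0.16, camera adjusted p = 0.387). Imprinted genes had 0 higher and 0 lower of 16 (0 and 0 over the list alone, median 0.11, camera adjusted p = 0.432). Targets of p53 had 0 higher and 0 lower of 25 (0 and 0 over the list alone, median 0.064, camera adjusted p = 0.876). The senescence and secretory list had 1 higher and 0 lower of 19 (1 and 0 over the list alone, median 0.10, camera adjusted p = 0.184). DNA replication and G1/S genes had 1 higher and 0 lower of 24 (2 and 0 over the list alone, median 0.15, camera adjusted p = 0.485). DNA methylation machinery had 2 higher and 0 lower of 11 (3 and 1 over the list alone, median 0.16, camera adjusted p = 0.557).

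Of the other lists at week 20, NRF2 and glutathione genes had 2 higher and 1 lower of 21 (3 and 2 over the list alone, median 0.057, camera adjusted p = 0.485). Interferon response genes had 0 higher and 1 lower of 28 (0 and 1 over the list alone, median -0.048, camera adjusted p = 0.694). Neutrophil markers had 0 higher and 0 lower of 11 (0 and 0 over the list alone, median 0.23, camera adjusted p = 0.374). B and plasma cell markers had 0 higher and 0 lower of 7 (2 and 0 over the list alone, median 0.28, camera adjusted p = 0.104), and an adjusted p of 0.0465 with no filter on dim probes, where it was 0.063 for T and NK markers, 0.408 for germline genes and 0.0871 for male-biased genes. Endothelial markers had 1 higher and 0 lower of 20 (1 and 0 over the list alone, median 0.071, camera adjusted p = 0.276). Erythroid genes had 0 higher and 0 lower of 10 (0 and 0 over the list alone, median -0.042, camera adjusted p = 0.833). Bile acid genes had 1 higher and 0 lower of 17 (1 and 2 over the list alone, median -0.18, camera adjusted p = 0.446). Fatty acid synthesis genes had 0 higher and 0 lower of 15 (0 and 0 over the list alone, median 0.020, camera adjusted p = 0.891). Pericentral hepatocyte genes had 0 higher and 0 lower of 14 (0 and 0 over the list alone, median -0.032, camera adjusted p = 0.78). Periportal hepatocyte genes had 0 higher and 0 lower of 16 (0 and 0 over the list alone, median 0.20, camera adjusted p = 0.108). Female-biased liver genes had 1 higher and 0 lower of 9 (2 and 0 over the list alone, median 0, camera adjusted p = 0.516) with a mean of 0.53. The sex chromosome transcripts had 0 higher and 0 lower of 5 (0 and 0 over the list alone, median -0.20, camera adjusted p = 0.60).

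Differences at weeks 4 and 8 were alike across genes, and those of week 20 less so. Pearson's r across the 10733 genes, which are not independent replicates, was 0.753 for weeks 4 and 8, 0.354 for weeks 8 and 20 and 0.312 for weeks 4 and 20. At weeks 4 and 8, 1329 genes were higher at both weeks and 1068 lower at both, against 395 and 320 expected from independent lists, and 35 had opposite signs. Weeks 8 and 20 shared 197 higher and 115 lower genes, against 91.8 and 57.4 expected, with 63 of opposite sign. Weeks 4 and 20 shared 154 higher and 74 lower genes, against 54.6 and 29.6 expected, with 38 of opposite sign. Over the 2918 genes past the threshold at week 4, the median difference in the week 4 direction was 0.78 at week 4, 0.90 at week 8 and 0.11 at week 20, and 95.6% kept their sign at week 8 and 65.4% at week 20.

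The change of the knockout effect from week 4 to week 8 asks whether the difference itself grew or turned with age. Igf2 (5.85 ± 0.65), H19 (5.82 ± 0.56), Cyp2b9 (5.71 ± 1.22), Gpc3 (5.40 ± 0.55) and Slc7a11 (5.11 ± 0.41) had the largest increases of the effect. Elovl3 (-6.93 ± 0.58), Mup4 (-6.13 ± 0.59), Nat8 (-5.87 ± 0.32), Cyp7b1 (-5.27 ± 0.50), a sterol hydroxylase, and Cyp4a12b (-5.24 ± 0.50) had the largest downward changes. Afp and Uhrf1 changed by 2.86 ± 0.44 and 2.04 ± 0.53, while Dnmt1, Dnmt3b and Cdkn1a passed no threshold, at -0.053 ± 0.27, -0.075 ± 0.50 and 2.08 ± 0.94. The effect increased for 598 genes and decreased for 361. A total of 11 lists passed under both settings of the list test. Fetal liver and female-biased genes shifted up (median changes 3.37 and 3.13, camera adjusted p = 1.1e-12 and 4.4e-07, 0.0070 and 0.0305 with an estimated correlation). Mitosis and matrix genes did too (median changes 1.84 and 1.18, camera adjusted p = 1.1e-12 and 4.3e-17, 0.0358 and 0.0249 with an estimated correlation). The mitosis list was not tested within a genotype. Neutrophil and replication lists shifted up (median changes 1.54 and 0.84, camera adjusted p = 3.3e-08 and 2.9e-09, 0.0305 and 0.0368 with an estimated correlation). So did B and plasma cell markers (median change 0.69, camera adjusted p = 0.00569, 0.0354 with an estimated correlation). Senescence and T and NK cell lists shifted less (median changes 0.58 and 0.55, camera adjusted p = 2.3e-04 and 8.8e-05, 0.0305 each with an estimated correlation). Male-biased genes (median change -2.38, camera adjusted p = 4.5e-19, 0.0070 with an estimated correlation) and bile acid genes (median change -0.40, camera adjusted p = 2.8e-04, 0.0353 with an estimated correlation) shifted down. The call of Uhrf1 ended when values were floored at 1 and quantile normalized again (adjusted p = 0.0549) and with the replicate block (0.0863).

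From week 8 to week 20, 9 of these 11 lists changed in the opposite direction with the preset correlation, and 3 of them also with an estimated one. Female-biased genes (median change -0.57, camera adjusted p = 0.0652, 0.35 with an estimated correlation) and B and plasma cell markers (median change -0.26, camera adjusted p = 0.207, 0.264 with an estimated correlation) passed under neither. The effect increased most for Rgs16 (7.11 ± 1.48), Hsd3b5 (6.67 ± 0.94), Sult2a8 (6.36 ± 0.54), Thrsp (5.97 ± 0.75) and Elovl3 (5.52 ± 0.58), genes that were low in knockout livers at week 8. It decreased most for H19 (-8.86 ± 0.56), Lcn2 (-6.93 ± 1.69), Slc7a11 (-6.89 ± 0.41), Igf2 (-6.58 ± 0.65) and Ly6d (-6.21 ± 0.48). Uhrf1, Afp and Cdkn1a also changed downward, with values of -3.33 ± 0.53, -3.74 ± 0.44 and -3.66 ± 0.94, and Dnmt1 and Dnmt3b passed no threshold (-0.28 ± 0.27 and -0.71 ± 0.50). The effect increased for 1525 genes and decreased for 1817. Under both settings of the list test, fetal liver genes (median change -3.87, camera adjusted p = 3.3e-08, 0.0249 with an estimated correlation) and matrix genes (median change -1.36, camera adjusted p = 1.2e-11, 0.0381 with an estimated correlation) shifted down. The senescence list (median change -1.21, camera adjusted p = 8.1e-06, 0.0144 with an estimated correlation) and biliary markers (median change -1.12, camera adjusted p = 0.00193, 0.0305 with an estimated correlation) did as well. With the preset correlation alone, macrophage markers (median change -2.03, camera adjusted p = 2.3e-13, 0.0624 with an estimated correlation) and interferon genes (median change -1.60, camera adjusted p = 1.4e-11, 0.0559 with an estimated correlation) shifted down. Germline genes (median change -1.43, camera adjusted p = 8.1e-06, 0.0653 with an estimated correlation) did the same. Hepatocyte genes (median change 0.81, camera adjusted p = 1.0e-06, 0.079 with an estimated correlation) and male-biased genes (median change 1.85, camera adjusted p = 7.0e-07, 0.0597 with an estimated correlation) shifted up.

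From week 4 to week 20 the knockout effect increased for 653 genes and decreased for 776. The largest increases were Rgs16 (6.20 ± 1.48), Inmt (5.16 ± 0.96), Upp2 (4.32 ± 0.98), Thrsp (4.26 ± 0.75) and Lpin1 (3.81 ± 0.63), a regulator of fat synthesis. The largest decreases were Lcn2 (-6.01 ± 1.69), Slpi (-5.53 ± 1.04), Pkd1l2 (-5.47 ± 0.45), Gstp2 (-5.33 ± 0.69) and Nat8 (-4.98 ± 0.32). H19 decreased (-3.04 ± 0.56), and Dnmt1, Dnmt3b, Uhrf1, Afp, Igf2 and Cdkn1a passed no threshold, at -0.33 ± 0.27, -0.79 ± 0.50, -1.29 ± 0.53, -0.88 ± 0.44, -0.73 ± 0.65 and -1.57 ± 0.94. Without control week 20 replicates 3 and 4, 742 genes changed and Lcn2 was at -2.03 (adjusted p = 0.0513). Its week 8 to 20 change partly rests on these controls too. The adjusted p of Lcn2 was also 0.0507 with robust estimation and 0.0551 with the replicate block. That of Uhrf1 was 0.0288 with an offset of 50, 0.047 with array weights and 0.0472 and 0.0249 without control week 20 replicate 1 or knockout week 4 replicate 1, and that of Cdkn1a (-2.37) 0.047 without control week 20 replicate 1. When values were floored at 1 and quantile normalized again the adjusted p was 0.20 for H19 and 0.076 for Slpi.

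Age changes within a genotype show how each liver matured. In control livers from week 4 to week 8, Cyp4a12b (6.81 ± 0.36), Cyp4a12a (6.17 ± 0.67), Elovl3 (5.44 ± 0.41), Nat8 (5.04 ± 0.23) and Nox4 (4.63 ± 0.32) rose most. Cyp2b9 (-7.71 ± 0.86), Cyp2b13 (-6.85 ± 0.40), Igf2bp3 (-4.86 ± 0.18) and Hao2 (-4.52 ± 0.38) were among the largest falls. At week 8, 342 genes were higher and 514 lower than at week 4. H19 and Uhrf1 fell with age in controls (-3.86 ± 0.39 and -1.86 ± 0.38), and Dnmt1, Dnmt3b, Afp, Igf2 and Cdkn1a passed no threshold (0.078 ± 0.19, -0.63 ± 0.36, -0.33 ± 0.31, -1.13 ± 0.46 and -1.88 ± 0.66). Cdkn1a passed with array weights (0.0174) and with only the 8 arrays (0.0097), and Igf2 with a floor of 1 (0.0496) and the replicate block (0.0217). Without control week 4 replicate 4 the count was 570. In knockout livers over the same weeks, Slc7a11 (5.11 ± 0.29), Igf2 (4.73 ± 0.46), Klra17 (3.13 ± 0.38), Gpc3 (3.06 ± 0.39) and Mogat2 (2.96 ± 0.25) rose most. Dio1 (-2.91 ± 0.44), Sult2a8 (-2.80 ± 0.38), Mup2 (-2.79 ± 0.41) and Alb (-2.76 ± 0.16) were among the largest falls, with 534 genes higher and 431 lower. Afp and H19 rose by 2.54 ± 0.31 and 1.96 ± 0.39, and Dnmt1, Dnmt3b, Uhrf1 and Cdkn1a passed no threshold (0.024 ± 0.19, -0.71 ± 0.36, 0.18 ± 0.38 and 0.20 ± 0.66). Without knockout week 4 replicate 4 the count was 585, and with values floored at 1 and normalized again the adjusted p of H19 was 0.13.

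From week 8 to week 20, control livers changed in 3 genes by limma, and 957 genes had an unadjusted p under 0.05. Acin1 (0.87 ± 0.14, adjusted p = 0.0128) and the unnamed model LOC56628 (0.98 ± 0.13, adjusted p = 0.00126, named after its values were seen) rose, and Calml4 (-1.43 ± 0.26, adjusted p = 0.0487) fell. Another Acin1 probe gave -0.21 ± 0.20, and the calls of Acin1 and Calml4 ended when single arrays were left out, with adjusted p values of 0.111 and 0.17 without control week 8 replicate 2. Dnmt1, Dnmt3b, Uhrf1, Afp, H19, Igf2 and Cdkn1a differed by -0.20 ± 0.19, 0.19 ± 0.36, 0.27 ± 0.38, 0.30 ± 0.31, 0.25 ± 0.39, 0.14 ± 0.46 and -0.21 ± 0.66 in controls. The count was 1 without control week 8 replicate 2 or 4 or control week 20 replicate 3, 24 and 64 without control week 20 replicates 1 and 2, and 34 without control week 20 replicates 3 and 4 together. In knockout livers 4616 genes changed over the same weeks, 2230 higher and 2386 lower at week 20. Hsd3b5 (6.14 ± 0.66), Mup4 (6.10 ± 0.42), Sult2a8 (6.06 ± 0.38), Thrsp (5.19 ± 0.53) and Mup5 (4.87 ± 0.40) rose most. H19 (-8.61 ± 0.39), Slc7a11 (-6.83 ± 0.29), Igf2 (-6.44 ± 0.46), Cbr3 (-5.60 ± 0.31) and Ly6d (-5.35 ± 0.34) fell most. Uhrf1, Afp, Cdkn1a and Dnmt1 fell (-3.06 ± 0.38, -3.44 ± 0.31, -3.86 ± 0.66 and -0.48 ± 0.19), and Dnmt3b passed no threshold (-0.52 ± 0.36). The call of Dnmt1 (adjusted p = 0.0469) ended without any of 6 single arrays, with an adjusted p of 0.15 without knockout week 20 replicate 2.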

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

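The tests of a larger spread at week 20, of the loss of the knockout pattern, of delayed maturation and of a lower share of hepatocytes were chosen after the results they concern were seen, and the other tests in this part before.

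The effect of the knockout changed with age by a test of the difference itself. From week 4 to week 8 it changed in 959 genes, more than in any other of 100 splits of the ages drawn within genotype. The next split gave 303. From week 8 to week 20 it changed in 3342 genes (highest other split 1939, 1 of 100 as large), and from week 4 to week 20 in 1429 (highest other 344, 1 of 100 as large). In each case this is the smallest share 100 splits allow. Exchanging genotypes gave 35 splits of 8 arrays at each week. The real split gave 2918, 5247 and 608 genes at weeks 4, 8 and 20, the highest others 11, 3 and 108, and 1 split of 35 reached each real count, which excludes chance. For age within a genotype, the real and highest other counts were 856 and 0 in controls and 965 and 279 in knockouts from week 4 to 8, and 4616 and 728 in knockouts from week 8 to 20, with 1 of 35 splits as large in each case. From week 8 to 20 in controls, 3 of 35 splits gave at least the real 3 genes, so chance cannot be excluded. The highest other split there called 128 genes and set control week 20 replicates 3 and 4, with control week 8 replicates 2 and 3, against the rest, which points to a structure of these arrays other than age.

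The smaller number of genes at week 20 was weighed against 3 explanations. A larger spread between week 20 arrays would leave the differences in place, but the median difference of the week 4 genes at week 20 was 0.127 of that at week 8, and between 0.0941 and 0.160 with any single array left out. Control replicates 3 and 4, which stood apart, do not account for it, since 306 genes passed without them against 5247 at week 8, and the median difference of the week 4 genes at week 20 was then 0.210 of that at week 8. Loss of most of the knockout pattern by week 20 is a candidate explanation, since this ratio was at most 0.210 in these fits, over genes chosen at another week. A change in which cells carry the deletion stays open, since dilution of knockout cells could not be decided (interquartile range 0.982). Age of the mice and other differences between the cohorts stay open and were not tested.

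Lower male-biased and higher female-biased genes at week 8 were weighed next. Knockout replicate 4 lacked the Y-linked signal of Eif2s3y, but without it the male-biased median was -2.21 against -2.23 with it. Delayed maturation would let male-biased genes rise more slowly, but their median change from week 4 to week 8 in knockout livers was -0.30, at most -0.016 with any single array left out, against 1.65 in controls. The pattern may reflect a loss of the adult male liver program, a hypothesis found and tested on the same arrays. The log2 signal of Eif2s3y was 9.13 to 9.27 on the other knockout arrays and 8.80 to 9.52 on the control arrays of week 8, so a difference in sex is not the whole cause. Hormone levels stay open.

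Higher macrophage, matrix and T cell lists at week 8 were weighed against a lower share of hepatocytes, which would raise the markers of every other cell type alike. The endothelial median lay at -2.37 relative to the macrophage median, with at most -0.10 for endothelial and at least 2.02 for macrophage markers when single arrays were left out. So the markers of other cell types did not rise alike. This argues against that explanation as the whole cause only if endothelial genes were not lowered for another reason, which was not tested. A shift from RNA quantity or normalization cannot be told apart, since the median difference over all tested genes, -0.067, is held near 0 by quantile normalization itself. An influx or activation of these cells may underlie the rise and was not tested.

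Genes whose effect changed from week 4 to 8 included Igf2 (5.85), H19 (5.82), Cyp2b9 (5.71), Gpc3 (5.40), Slc7a11 (5.11), Afp (2.86) and Uhrf1 (2.04) upward and Elovl3 (-6.93), Mup4 (-6.13), Nat8 (-5.87), Cyp7b1 (-5.27) and Cyp4a12b (-5.24) downward. From week 8 to week 20 they were Rgs16 (7.11), Hsd3b5 (6.67), Sult2a8 (6.36), Thrsp (5.97) and Elovl3 (5.52) upward and H19 (-8.86), Lcn2 (-6.93), Slc7a11 (-6.89), Igf2 (-6.58), Ly6d (-6.21), Afp (-3.74), Cdkn1a (-3.66) and Uhrf1 (-3.33) downward. From week 4 to 20 they were Rgs16 (6.20), Inmt (5.16), Upp2 (4.32), Thrsp (4.26) and Lpin1 (3.81) upward and Lcn2 (-6.01), Slpi (-5.53), Pkd1l2 (-5.47), Gstp2 (-5.33), Nat8 (-4.98) and H19 (-3.04) downward. Both Lcn2 values lean on control week 20 replicates 3 and 4. List medians that changed under both settings from week 4 to 8 were those of fetal liver genes (3.37), female-biased genes (3.13), mitosis (1.84), neutrophil markers (1.54), matrix genes (1.18), replication (0.84), B and plasma cell markers (0.69), senescence (0.58), T and NK cell markers (0.55), bile acid genes (-0.40) and male-biased genes (-2.38). From week 8 to week 20 they were fetal liver genes (-3.87), matrix genes (-1.36), senescence (-1.21) and biliary markers (-1.12).

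Single arrays far from the other 3 of their group, by Dixon's test at the 95% level, were found in 42 of 624 groups tested, where chance gives about 1 in 20 groups, or 31.2. Control week 4 replicate 4, knockout week 4 replicate 4 and knockout week 8 replicate 4 were each found 6 times. Values are log2 signals. Knockout week 4 replicate 4 stood apart for Thrsp (8.39), Slpi (12.54), Gsta1 (11.99), Sult2a8 (9.56), Gpnmb (8.05) and Cd74 (10.14). Knockout week 4 replicate 1 did for Dnmt3b (7.03), Kif22 (7.73) and Plk1 (8.08), and replicate 5 for Gstp2 (13.94) and Phlda2 (6.84). Control week 4 replicate 4 stood apart for Lcn2 (8.70), Mup4 (5.80), Cyp7b1 (8.73), Ces1e (8.81), the mean of imprinted genes (7.64) and that of bile acid genes (10.03), with replicate 3 for Slc10a1 (7.54) and replicate 1 for Impact (7.55). In controls of week 8 it was replicate 2 for Fcer1g (8.50), replicate 3 for Rhox5 (5.20), Lum (7.40) and Iap (10.52), replicate 4 for p53 targets (7.48), and replicate 5 for Nat8 (9.74) and Bicc1 (4.35). Knockout week 8 replicate 4 stood apart for Eif2s3y (4.00), Ddx3y (7.41), Xist (7.20), Cyp2b9 (11.09), the sex chromosome list (5.52) and erythroid genes (7.80), with replicate 1 for Igf2bp3 (9.08) and neutrophil markers (5.88) and replicate 3 for pericentral genes (9.29). At week 20 it was control replicate 3 for Afp (5.23), control replicate 2 for Igf2 (5.61), and knockout replicate 1 for Sult2a8 (10.70) and imprinted genes (7.12), replicate 2 for Cela1 (8.35) and replicate 4 for Gstp2 (12.37) and Bicc1 (6.57).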

How the results depend on the processing

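A floor of 16 and the omission of both control week 20 replicates 3 and 4 were chosen after the data had been seen, and the other alternatives before. The cause of a change was not tested, except that leaving arrays out or fitting 8 arrays alone lowers the number of arrays. Over 19 summary results, the alternatives left 370 values within 1.5 times a count or 1 SD of a value and moved 34. Lists, called or not, stayed on their side of the threshold in 1142 cases, lost a call in 84 and gained one in 14, named genes stayed in 6485, lost in 121 and gained in 17, and no called direction reversed. With no filter on dim probes, 390 genes passed at week 20 (608 in the main setting) and 5 from week 8 to 20 in controls (3), and the correlation of weeks 4 and 8 was 0.726 (0.753). With a floor of 1 and a new quantile normalization that correlation was 0.687, and 6 genes passed from week 8 to 20 in controls. That comparison gave 7 with all probes, 6 with array weights and 9 with the floor of 16. Array weights gave 1517 genes from week 4 to 8 in controls (856). With only the 8 arrays compared, 131 genes passed at week 20, 1339 from week 4 to 8 in controls and 0 from week 8 to 20 in controls, where limma gave 957 at an unadjusted p under 0.05 in the fit of 24 arrays. The replicate number as a block gave 266 genes at week 20, 430 for the change of the effect from week 4 to 8 (959), 489 and 498 from week 4 to 8 in controls and knockouts (965), and 0 from week 8 to 20 in controls. Deviations from group means in control and knockout arrays of the same number correlated little. Values were -0.120 to 0.0062, -0.032 to 0.041 and -0.145 to -0.00072 at weeks 4, 8 and 20. Without both doubtful controls 306 genes passed at week 20, 742 for the change from week 4 to 20 (1429) and 34 from week 8 to 20 in controls. An estimated inter-gene correlation left 0, 1 and 0 lists at weeks 4, 8 and 20 (18, 22 and 8).

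Leaving out single arrays gave 2367 to 2849 genes at week 4, 4627 to 5055 at week 8 and 284 to 718 at week 20, with 284 and 306 without control replicates 3 and 4 and 331 and 370 without knockout replicates 2 and 3. The change of the effect passed in 700 to 994 genes from week 4 to 8, 2970 to 3469 from week 8 to 20 and 1033 to 1661 from week 4 to 20. Age changed 570 to 802 genes from week 4 to 8 in controls (570 without week 4 replicate 4), 585 to 1146 in knockouts (585 without week 4 replicate 4) and 4023 to 4460 from week 8 to 20 in knockouts. In controls from week 8 to 20 it was 1 to 64, with 24 and 64 without week 20 replicates 1 and 2 and 1 each without week 20 replicate 3 and week 8 replicates 2 and 4. Dnmt1 ranged from -0.38 to -0.11 at week 4, -0.35 to -0.27 at week 8 and -0.70 to -0.48 at week 20. Lists called were 14 to 18, 21 to 23 and 7 to 10. A block for the chip was not run, since the labels give no chip, nor were the planned settings on non-normalized signals and detection p-values, whose columns match no sample. Signal over background limits dim genes, since an intensity under 16.3 was not told from noise and the added 16 shrinks their differences.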

Other observations

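All tests of hypotheses in this part were chosen before their results were seen, while the genes Asns, Psat1, Slc1a4, Iap and Nat8 were singled out at these weeks after their values were seen. At week 8 rises were seen for Slc1a4 (5.16 ± 0.32), a carrier of neutral amino acids, Psat1 (3.52 ± 0.42), an enzyme of serine synthesis, and Asns (3.45 ± 0.61), asparagine synthetase, whose 2 other probes gave 1.23 ± 0.33 and 3.22 ± 0.57. The probe Iap rose by 3.99 ± 0.23 at week 4 and 4.83 ± 0.23 at week 8, and its target is not given in the sources used here. Nat8, which rose with age in control livers from week 4 to 8, was already higher in knockout livers at week 4 (5.48 ± 0.23).

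Of the genes below background on all 12 control arrays, 79 were above it in knockout livers at week 4. At week 8, 77 of them were called and at week 20, 15. Of the 79, 7 were above background on 4 knockout arrays of week 20 and 32 on none.

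Dilution of 1 pool of knockout cells by week 20 could lower all of these genes by 1 factor. In the 14 brightest, at least 16 times background, the log2 ratio of week 20 to week 4 signal had a median of -4.47 and an interquartile range of 0.982. Since 8 of the 14 lay at background at week 20, which bounds their ratio, dilution cannot be told apart from silencing of single genes. Of those above background at week 20, Magea2 kept 33.2% of its week 4 signal, Bglap3 6.92% and Pkd1l2 1.77%.

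A wider rise of ATF4 targets might underlie the rises of Asns, Psat1, Slc1a4 and Slc7a11. The 21 measured targets not used to form this hypothesis gave a camera p of 0.695 at week 8 (0.781 with an estimated correlation), a median of 0.23, 4 higher and 5 lower, which argues against a rise of the targets as a whole.

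A different time of day at collection could lower Rgs16, Upp2, Lpin1 and Thrsp. At week 8, 3 clock genes were called, with medians of -0.81 for the genes peaking with Dbp and -0.027 for Arntl and Clock, the 2 measured of the opposed set, so the time of day cannot be told apart from an effect of the knockout.

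Genes that rose at week 4 may cluster along the chromosome. The next tested gene also rose for a share of 0.174 of them, leaving out neighbours of the same name stem, against a median of 0.148 in 1000 shuffled orders, of which 0 gave as large a share. For genes that fell it was 13.6%, and 77 of the 1000 orders gave as much, which is below the 95% criterion. Whether rises and falls differ in this was not tested. Shared control of neighbours and probes that detect both were not tested.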
